A study of Mus musculus with 24 samples.

How the data were processed

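Total RNA from mouse liver, 200 ng per array, was hybridised to an Affymetrix mouse expression array with 45101 probe sets. The 24 arrays form 8 groups of 3, defined by the genotype and treatment in the sample titles, and the number in each title differs, so each array was taken as a separate animal. A first submission holds 18 arrays of WT, KO and GS mice, aged 8 to 9 weeks and kept for 3 weeks on an iodine-poor diet with 0.02% methimazole, 0.5% perchlorate and 0.3% saccharin in the water. A later submission holds 6 arrays of Y147F mice, aged 10 to 11 weeks and given 0.05% methimazole and 1% perchlorate. T3 was injected at 20 µg per 100 g body weight in the first and at 200 ng per g, the same dose, in the later submission.

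Per the labels, the authors summarised the arrays with RMA, and the deposited values are log2 intensities, as the range of the 18 first-submitted columns also showed. The version of RMA is not given in the sources used here. In the 6 later columns nearly all values had lost their decimal mark. It was put back after the first digits that gave a value from 3 to 16, and a cell that a spreadsheet could also have turned from a short decimal into a day number was set missing, which left out 775 cells, 0.286% of these columns. The rule was tested by damaging the 18 intact columns in the same way: of 809324 values restored none was wrong. The damage used the rule's own assumptions, so this checks only that the steps were carried out correctly. Whether any later cell was altered in another way cannot be seen from the column, so the comparisons of WT, KO and GS were repeated without those arrays.

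A probe table paired 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none. Only the first were used, and each of the 18194 genes was represented by its probe set with the highest mean over all arrays. A gene was tested if it reached the 40th percentile of its array in at least 3 arrays, which kept 14162 genes, 232 of them with a missing cell. No probe coordinates were used. Gene positions served only to find the genes nearest to Thrb and to order genes along each chromosome.

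In R 4.3.3 with limma 3.58.1, 1 linear model with 8 group means was fitted to each gene, with empirical Bayes moderation, 16 residual and 4.28 prior degrees of freedom and no covariate. Contrasts were T3 against PBS within each genotype, the differences of these responses between genotypes, and the genotype differences among PBS mice. Tests were two-sided, adjusted by Benjamini and Hochberg over the genes of a contrast, and called at an adjusted p under 0.05. The genes named were, per T3 response, up to 12 with the largest rise and 12 with the largest fall among those called whose T3 arrays all lay on 1 side of the PBS arrays, and per other contrast up to 8 each way. Added to them were Thrb, Thra, all hepatic T3 targets and up to 4 members of a gene list with the smallest p, and clones without a name could be left out. The groups, contrasts, tests, gene lists, naming rule and most of the other settings tried were fixed before the data were examined.

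The 31 gene lists, covering pathways and cell types with 491 members, 440 of which had a probe set, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Lists with fewer than 5 measured genes were not tested. A score per array, the mean log2 value of a gene set, was compared between genotypes as T3 minus PBS by exact two-sided permutation of the genotype labels within each treatment, with 400 relabellings and a smallest p of 0.005. Gene sets for the score were called in a genotype outside the comparison, or were the fixed list of T3 targets. A comparison of 3 arrays with 3 by permutation cannot give a p below 0.1, so single comparisons of groups rest on limma. Overlaps used Fisher's exact test.

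The steps were tested on simulated data with 50 changed genes per fold size and the same spread per gene in all groups. For T3 in WT, 78% of 1.5-fold and 94% of 2-fold changes were recovered, and nothing was called when nothing had been changed. The settings chosen beforehand were quantile normalisation, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, a variance trend with robust moderation, a fit of only the arrays compared, array weights, a covariate for title numbers over 100000, a 2-fold threshold and leaving out each array in turn. Chosen after seeing the data were the fit of first-submitted arrays alone, the score of the T3 targets over all genotypes, and list tests on only the arrays compared. Probe sets without a single symbol entered no comparison and are counted in the closing section.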

Results

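Liver RNA of 24 hypothyroid male mice was measured on 24 microarrays, in 8 groups of 3. The groups combined 4 genotypes of the thyroid hormone receptor TRβ with an injection of T3, the active thyroid hormone, or of PBS alone, and livers were taken 6 h later. The genotypes were wild type (WT), a TRβ knockout (KO), a mutant with the changes E125G and G126S in the DNA-binding domain (GS), and a mutant with Y147F, which replaces a tyrosine linked to kinase signalling outside the nucleus. Comparing them asks how much of the liver's response to T3 needs the receptor, its binding to DNA, or that tyrosine. Values below are log2 intensities or log2 differences ± SE, with n = 3 arrays per group, and the number of arrays limits their precision. Array medians lay between 5.88 and 6.00, and arrays of a group correlated with each other at a mean r of 0.994 to 0.997. The first principal component, with 19.3% of the variance, ran from 0.23 to 0.36 in the T3 arrays of WT and Y147F and from -0.30 to -0.19 in their PBS arrays. In KO and GS it ran from -0.01 to 0.07 with T3 and from -0.12 to -0.05 with PBS. The second component, with 14.4% of the variance, separated KO and GS arrays (-0.30 to -0.08) from WT and Y147F arrays (0.10 to 0.35), with and without T3. The Y147F PBS replicate 3 stood apart on the third component, at -0.60.

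Thrb itself, read by 1 probe set, had group means from 6.54 in Y147F with T3 to 6.99 in KO with PBS, so the probe set did not show the loss of the receptor in KO. Where its probes lie relative to the deleted part was not examined, and the amino acid changes of the other mutants cannot be read from an expression array. Thra, which encodes the other thyroid hormone receptor, had means from 7.70 to 8.62 over its 3 probe sets. Its brightest probe set was lower with T3 in Y147F (-0.42 ± 0.12, adjusted p = 0.0241) and was not called in WT (-0.32 ± 0.12), KO (-0.28 ± 0.12) or GS (-0.18 ± 0.12). With only the arrays compared in the fit it was called in WT (adjusted p = 0.0469) and not in Y147F (0.0865).

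The first comparison asks what T3 did in 6 h to a hypothyroid liver with an intact receptor. In WT, Dio1, the deiodinase that converts and clears thyroid hormone, rose by 6.63 ± 0.28 (adjusted p = 2.37e-12). Without T3 its values in WT, 4.49 to 5.07, lay near the 25th percentile of their arrays (4.69 to 4.72), so differences of Dio1 from these arrays are rises over background and give no exact fold. Bcl3, a cofactor of NF-κB, rose by 2.82 ± 0.17, the mitochondrial glycerol phosphate dehydrogenase Gpd2 by 2.38 ± 0.14, and Idh3a, a subunit of the citric acid cycle's isocitrate dehydrogenase, by 2.21 ± 0.11. Socs2, the suppressor of cytokine signalling that growth hormone induces, fell most among the named genes (-3.71 ± 0.42, adjusted p = 2.35e-06), followed by Acot3, a peroxisomal acyl-CoA thioesterase (-3.43 ± 0.45). Further large rises were those of Frmd8 (3.21), the mitochondrial carrier Slc25a45 (2.70), the proapoptotic Bmf (2.65), the major urinary protein Mup10 (2.41), the stress gene Gadd45a (2.31), the organic anion transporter Slc22a7 (2.30) and the steroid hydroxylase Cyp17a1 (2.28). The metallothioneins Mt2 (-2.30) and Mt1 (-1.84), the nuclear receptor Nr4a1 (-2.24), the transglutaminase Tgm1 (-2.19), the activin subunit Inhbe (-2.19), the monooxygenase Fmo2 (-1.98), the ceramide synthase Cers6 (-1.93), the monocarboxylate transporter Slc16a5 (-1.73) and Nipal1 (-2.97) fell.

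Of the 17 measured members of a fixed list of hepatic T3 targets, 11 rose in WT and none fell, 13 rose adjusted over the list alone, and the list test gave an adjusted p of 2.15e-15 (1.92e-04 with an estimated correlation). Besides the genes above they included Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.77), the lipogenic genes Thrsp (1.36), Me1 (0.89) and Mlxipl (0.87), glucose-6-phosphatase G6pc (0.66), the thyroid hormone transporter Slc16a10 (0.46) and the transcription factor Klf9 (0.38). G6pc was not called with no filter on low values (adjusted p = 0.0533), nor Slc16a10 with the mean of its probe sets (0.19 and 0.136). Among 18 genes of fatty acid synthesis, 6 rose, 9 adjusted over the list alone, among them Agpat2 (1.16) and Srebf1 (0.69). That list's test gave an adjusted p of 5.87e-06, and an adjusted p = 0.677 with an estimated correlation. Of 16 genes of bile acid and sterol disposal, 6 rose and 1 fell (7 and 2 adjusted over the list alone). The sterol exporter Abcg8 rose by 1.06, Scarb1 by 0.60 and Cyp27a1 by 0.55, while the bile acid receptor Nr1h4 fell by 0.68. The test of this list gave an adjusted p of 0.0127, and an adjusted p = 0.162 with an estimated correlation.

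Of the 13 measured genes of growth hormone and IGF signalling, 2 rose and 4 fell in WT, and 4 rose and 5 fell adjusted over the list alone. The signal transducers Stat5a (2.02 ± 0.09) and Stat5b (1.45 ± 0.08) rose, and Igfals, which encodes the carrier of circulating IGF complexes, fell (-0.94 ± 0.12). Their list test, which asks for a common direction, gave an adjusted p of 0.827. Clock genes also moved both ways, with 2 of 17 higher and 4 lower, the same adjusted over the list alone, as Cry1 (0.81) and Per3 (0.58) rose and Nfil3 (-1.45) and Cry2 (-0.70) fell (list adjusted p = 0.572). The xenobiotic receptors Nr1i2 (-1.02) and Nr1i3 (-0.82) fell, as did the hepatocyte factor Hnf4a (-0.37) and Creb3l3 (-0.51), and the acute phase regulator Cebpb rose (1.19). Of 15 FOXO1-responsive genes 3 rose, 4 adjusted over the list alone (adjusted p = 0.025, and adjusted p = 0.599 with an estimated correlation), Gadd45a among them. Among 12 sinusoidal endothelial markers none was called by limma, 6 had an unadjusted p under 0.05, and the list had a median change of -0.20 and an adjusted p of 0.0231 (adjusted p = 0.685 with an estimated correlation).

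Across all 14162 genes tested, limma called 1505 in WT, 811 higher and 694 lower, of which 131 and 61 changed at least 2-fold. The groups of 3 arrays did not overlap for 1484 of the 1505, against 29.5% of all genes, where chance gives 10%. Mt1 (adjusted p = 0.106) and Mt2 (0.0543) lost their calls without the WT T3 replicate 1, and Cyp17a1 (0.0556) and Mt1 (0.085) lost them without the WT PBS replicate 2.

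**Figure D1:**
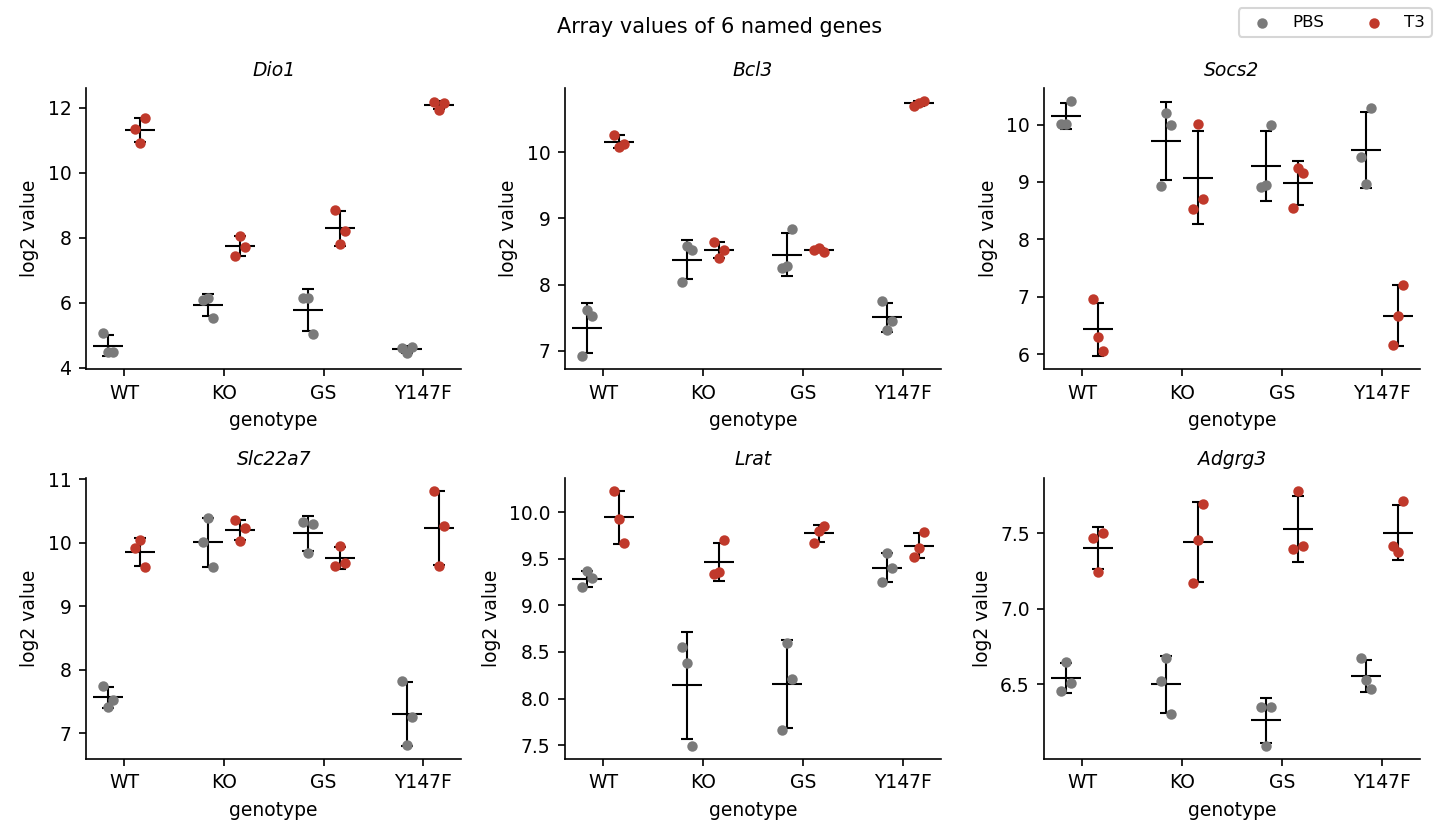
Log2 array values (vertical axis) of 6 genes by genotype (horizontal axis), with PBS arrays in grey and T3 arrays in red; points are single arrays, long bars group means and short bars ± SD, n = 3. Dio1 was 6.63 higher with T3 in WT and 1.82 higher in KO, and Slc22a7 was higher without T3 in KO than in WT by 2.44.

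The knockout shows what T3 did without TRβ. In KO, Dio1 still rose 3.54-fold (1.82 ± 0.28, adjusted p = 0.00383), and Lrat, which esterifies retinol, rose by 1.33 ± 0.22 (adjusted p = 0.00865). Slc25a45 (1.02 ± 0.13), the adhesion receptor Adgrg3 (0.95 ± 0.14), C1qtnf2 (0.76 ± 0.12), Art3 (0.76 ± 0.10) and the coenzyme Q gene Coq10a (0.70 ± 0.09) rose, and the small heat shock gene Hspb1 fell (-0.88 ± 0.12). Each of these 8 kept its call in all 6 fits that left out 1 array, and the unnamed 9030619P08Rik (3.30 ± 0.26) did as well. Gramd1c (0.89), Gbp3 (0.86), the trehalase Treh (0.79) and Pxdn (0.76) rose, and the intermediate filament gene Vim (-1.01), the magnesium transporter Slc41a2 (-0.90), Akap12 (-0.71), Ppl (-0.55), Cyp2c23 (-0.54) and Plp2 (-0.47) fell, each losing its call in at least 1 of those fits. Stat5a rose by 0.57 ± 0.09. Hspb1 was also lower in GS than in KO without T3, a difference that uses the same KO PBS arrays as its fall here.

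Of the 17 T3 targets only Dio1 was called in KO, and 3 were called adjusted over the list alone (list adjusted p = 1.06e-04, and adjusted p = 0.0648 with an estimated correlation). A further 10 lists passed the test with the preset correlation and none of them with an estimated one. Markers of other liver cells were among them and lay lower with T3. The medians were -0.24 for 13 Kupffer cell markers (adjusted p = 0.00537, and 0.633 with an estimated correlation), -0.16 for 12 sinusoidal endothelial markers (0.00213, and 0.424 with an estimated correlation), -0.28 for 12 stellate cell markers (0.0197, and 0.596 with an estimated correlation) and -0.26 for 9 cholangiocyte markers (0.00213, and 0.424 with an estimated correlation). Vim, a gene of such non-parenchymal cells, was called lower beside them. The KO PBS arrays also enter the marker differences of KO from WT and from GS given below, so these are not separate observations. Among stellate markers Lum (0.67), Col3a1 (0.64), Col1a2 (0.45), Rgs5 (0.44), Col1a1 (0.39), Pdgfrb (0.36) and Acta2 (0.14) stood above WT in KO without T3. Reln, Des, Dcn, Timp1 and Lrat did not. Limma called 25 genes in KO, 18 higher and 7 lower, and all 25 had non-overlapping groups, against 15.2% of all genes where chance gives 10%. With only the 6 KO arrays in the fit the count was 6 and Lrat was not called (adjusted p = 0.249), without the KO T3 replicate 1 it was 16, and 5 genes changed at least 2-fold.

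GS asks the same of a receptor altered in its DNA-binding domain. Here T3 raised Dio1 by 2.52 ± 0.28 (adjusted p = 8.51e-05), from PBS values of 5.03, 6.13 and 6.16, the lowest of which lay within the background range of WT, so no fold is given. It raised Lrat by 1.61 ± 0.22, Adgrg3 by 1.27 ± 0.14 and Coq10a by 0.76 ± 0.09. Art3 (0.75 ± 0.10), the phosphatase gene Pdp2, which activates pyruvate dehydrogenase (0.62 ± 0.08), and Gch1, which begins tetrahydrobiopterin synthesis (0.58 ± 0.09), also rose. These 7 genes and 9030619P08Rik (2.39 ± 0.26) were called in all 6 fits that left out 1 array. Adamdec1 (1.18), Pxdn (0.90), the vitamin C transporter Slc23a2 (0.80) and Sel1l3 (0.78) rose, and Adam23 (-0.68) and Rtn2 (-0.45) fell, each losing its call in at least 1 of those fits. Stat5a rose by 0.58 ± 0.09. Among the 17 T3 targets Dio1 alone was called, and 4 were called adjusted over the list alone (list adjusted p = 0.0647). Kupffer cell markers lay higher with T3, with a median of 0.29 (adjusted p = 7.69e-04, and adjusted p = 0.62 with an estimated correlation), and sinusoidal endothelial markers lower at -0.14 (7.33e-04, and 0.392 with an estimated correlation). The calls numbered 21, 19 higher and 2 lower, all with non-overlapping groups, against 13.1% of all genes where chance gives 10%. That count was 2 with only the 6 GS arrays in the fit, where Dio1 (adjusted p = 0.0566) and Lrat (0.0519) were not called, and 33 with array weights, and it was 10 without the GS T3 replicate 2, 12 without the GS T3 replicate 3, 10 without the GS PBS replicate 2 and 13 without the GS PBS replicate 3.

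The genes that T3 raised in KO and in GS were set beside each other. Of the 18 and 19 called higher, 9 were the same, where 0.0241 would be expected of unrelated lists (Fisher's exact two-sided p = 7.09e-23). Of each set 14 were also called higher in WT, where 1.03 and 1.09 would be expected. Adgrg3 rose by 0.87 in WT and 0.95 in Y147F, Art3 by 0.88 and 0.64, and Pxdn by 0.78 and 0.76, beside the rises in KO and GS given above, and these 3 genes were picked for this comparison after their values were seen. Coq10a rose by 1.97 in WT and 1.96 in Y147F, and its response differed from WT by -1.27 ± 0.13 in KO (adjusted p = 4.3e-06) and -1.21 ± 0.13 in GS (adjusted p = 6.07e-06). With the mean of its probe sets the difference of Coq10a in GS was -0.30 and not called (adjusted p = 0.14). For Lrat the T3 difference was 0.66 ± 0.22 in WT and 0.24 ± 0.22 in Y147F, beside a lower level without T3 in KO (-1.15 ± 0.22) and GS (-1.13 ± 0.22) than in WT.

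Whether the mutants responded differently from WT was tested on the difference of the T3 responses. In KO the response of Dio1 differed from that in WT by -4.80 ± 0.40, a size that depends on the background level of Dio1 in WT without T3. That of Bcl3 differed by -2.67 ± 0.24 and that of Gpd2 by -1.90 ± 0.20, while Socs2 (3.08 ± 0.59) and Acot3 (4.16 ± 0.64), which fell in WT, were higher by this measure. Without T3, KO already stood above WT for Bcl3 and Gpd2 and below it for Acot3, so part of these differences lies in the PBS groups. GS differed from WT by -4.11 ± 0.40 for Dio1, -2.75 ± 0.24 for Bcl3, -1.90 ± 0.20 for Gpd2, 3.42 ± 0.59 for Socs2 and 2.55 ± 0.64 for Acot3. Thus 437 genes were called in KO, 146 with a higher and 291 with a lower response, and 414 in GS, 137 and 277. Of the T3 targets 5 of 17 had a lower response in KO, 7 adjusted over the list alone (adjusted p = 1.76e-11, and 0.00104 with an estimated correlation), and 6 in GS, 8 adjusted over the list alone (1.40e-15, and 1.79e-04 with an estimated correlation). Stat5a differed by -1.45 in KO and -1.44 in GS, Stat5b by -1.16 and -1.12, and Mlxipl by -0.80 and -0.90. Nr1i2 was higher by 1.16 and 0.99. Of 18 genes of fatty acid synthesis 2 had a lower response in KO, 5 adjusted over the list alone (adjusted p = 0.00606, and adjusted p = 0.754 with an estimated correlation), and 5 in GS, 6 adjusted over the list alone, among them Thrsp (-1.51), Agpat2 (-1.18) and Srebf1 (-0.96; list adjusted p = 4.59e-08, and adjusted p = 0.359 with an estimated correlation). Kupffer cell markers moved in the same comparison of GS with WT, with a median of 0.44 over 13 genes (adjusted p = 0.0244, and adjusted p = 0.734 with an estimated correlation), none called by limma and 1 at an unadjusted p under 0.05. Differences of at least 2-fold numbered 120 in KO and 126 in GS, and the call of Acot3 in GS was lost in 11 of the 12 fits that left out 1 array.

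Selecting genes on arrays outside the comparison gave the size of these differences. The mean of the 782 genes that T3 raised in Y147F rose by 0.59 ± 0.03 in WT, 0.12 ± 0.01 in KO and 0.12 ± 0.01 in GS, so that the response was 20.0% of that of WT in KO and 19.6% in GS. KO and GS each differed from WT by -0.47 ± 0.03 (exact two-sided permutation p = 0.005, the smallest of 400 relabellings; Benjamini-Hochberg p = 0.0075 over 18 tests). With only genes that changed at least 2-fold in Y147F the differences were -1.18 in KO and -1.24 in GS. For the 862 genes that fell in Y147F the change was -0.39 in WT, -0.07 in KO and -0.07 in GS (exact permutation p = 0.005 for both mutants), and with the 2-fold selection KO and GS differed from WT by 1.27 and 1.13. KO and GS did not differ detectably from each other on either set (exact permutation p = 0.89 and p = 0.87), and no gene passed limma's test of GS against KO, where 809 had an unadjusted p under 0.05. Of the gene lists 5 passed that test with the preset correlation and none with an estimated one. The response in GS was higher than in KO for Kupffer cell markers (median 0.51, adjusted p = 9.19e-07), stellate cell markers (0.32, 0.014), cholangiocyte markers (0.23, 0.014) and immediate early genes (0.38, 0.0352), and lower for fatty acid synthesis (-0.29, 6.07e-04). With an estimated correlation the adjusted p was 0.492 for the first 3 and the last of these lists and 0.493 for immediate early genes. The KO PBS arrays behind the lower marker medians with T3 in KO enter this comparison too. Without T3 the 782 genes already stood 0.21 ± 0.03 higher in KO and 0.23 ± 0.03 higher in GS than in WT, and with T3 their mean of 9.29 in WT lay above 9.04 in KO and 9.05 in GS.

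**Figure D2:**
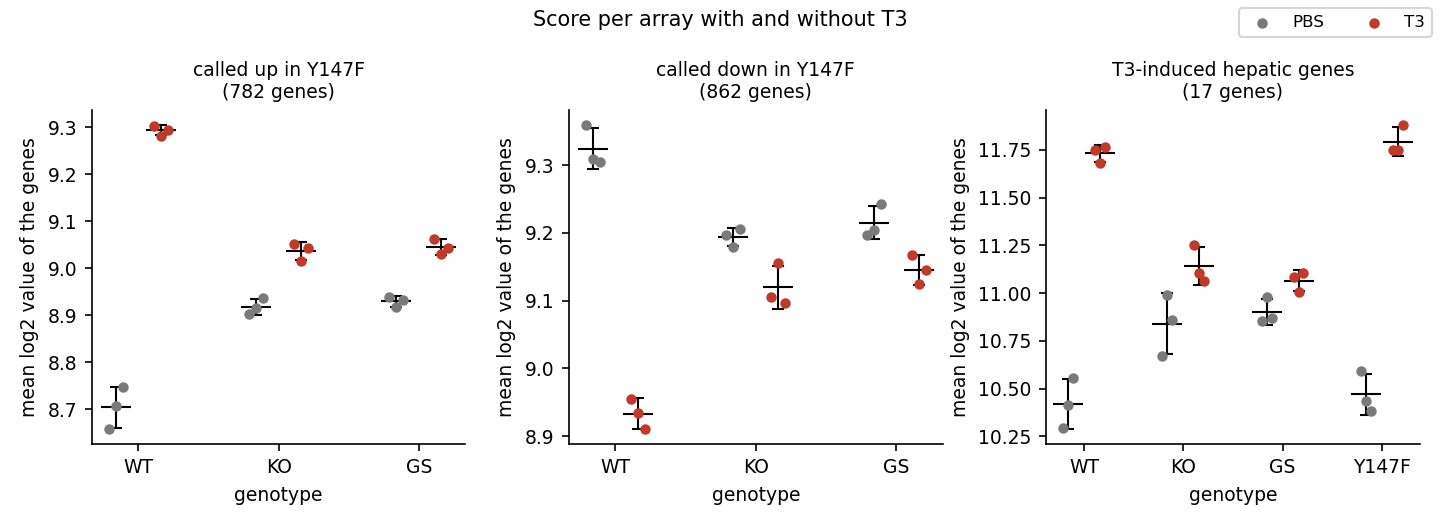
Mean log2 value per array (vertical axis) of genes called higher or lower by T3 in Y147F and of 17 hepatic T3 targets, by genotype (horizontal axis), with PBS in grey and T3 in red; long bars are means, short bars ± SD, n = 3. For the 782 genes the T3 and PBS means were 9.29 and 8.70 in WT, 9.04 and 8.92 in KO, and 9.05 and 8.93 in GS.

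Y147F asks whether the response needs that tyrosine. Dio1 rose by 7.52 ± 0.28 in Y147F, again from background, with PBS values of 4.46 to 4.64 beside 25th percentiles of 4.63 to 4.69. Bcl3 rose by 3.24 ± 0.17, Slc25a45 by 3.21 ± 0.13 and Slc22a7 by 2.94 ± 0.25, and Acot3 (-3.99 ± 0.45) and Socs2 (-2.89 ± 0.42) fell. Mup10 (3.10), Frmd8 (2.96), Bmf (2.34), the immunoglobulin gene Ighm (2.19; 2.19 in WT), the autophagy gene Trp53inp2 (2.15), Stat5a (2.11) and the coenzyme A hydrolase Nudt7 (2.11) were the next largest named rises. Mt2 (-2.75), Nipal1 (-2.74), Tgm1 (-2.19), Fmo2 (-2.03), Mt1 (-1.97), Fam47e (-1.95), Cers6 (-1.90), Slc16a5 (-1.86) and the glycogen-targeting Ppp1r3g (-1.87) fell. Of the T3 targets 12 of 17 rose, 13 adjusted over the list alone (adjusted p = 4.12e-14, and 3.22e-04 with an estimated correlation), with Cyp7a1 (2.83-fold), Thrsp (1.10), Fasn (1.16) and Ppargc1a (0.51) among them. With array weights Fasn (adjusted p = 0.0653) and Ppargc1a (0.0644) were not called, nor was Cyp7a1 with the title number as a covariate (0.159). Fatty acid synthesis had 7 of 18 higher, 8 adjusted over the list alone (adjusted p = 2.12e-05, and adjusted p = 0.453 with an estimated correlation). Clock genes had 1 of 17 higher and 4 lower, 1 and 6 adjusted over the list alone (0.0495, and adjusted p = 0.425 with an estimated correlation), with Per1 at -1.44 and Nfil3 at -1.40. The growth hormone list had 2 of 13 higher and 4 lower, and 2 and 5 adjusted over the list alone, with Stat5b at 0.99 and Igfals at -0.82.

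Limma called 1644 genes in Y147F, 782 higher and 862 lower, 161 of them at least 2-fold. Groups did not overlap for 1598 of these, against 26.0% of all genes where chance gives 10%. With only the 6 Y147F arrays in the fit the count was 864, without the Y147F T3 replicate 1 it was 1086, and in both more genes rose than fell (458 and 406, and 623 and 463), and Ppp1r3g lost its call in 4 of the 6 fits that left out 1 array (without the Y147F PBS replicate 1 or 3 or the Y147F T3 replicate 1 or 2, adjusted p up to 0.17). Of the calls, 551 higher and 404 lower were shared with WT, where 44.8 and 42.2 would be expected, and none was called in opposite directions. Genes called higher in WT had a median of 0.49 there, 0.39 in Y147F, 0.10 in KO and 0.09 in GS, and genes called lower had -0.45, -0.37, -0.09 and -0.06. Across genes, which are not independent replicates, the responses of Y147F and WT had a Pearson r of 0.800 (Spearman 0.576), against 0.357 (0.306) for KO and 0.313 (0.215) for GS.

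No gene passed limma's test of a different T3 response in Y147F and WT, and 756 had an unadjusted p under 0.05. In simulated data the same test recovered 92% of 2-fold and 66% of 1.5-fold differences, so smaller differences would often have been missed. The simulation gave all groups the same spread per gene. Array weights of the real Y147F arrays ran from 0.40 to 3.36, so these shares may be too high for them. The mean of the 17 T3 targets, Dio1 included, rose by 1.31 in WT and 1.32 in Y147F, a difference of 0.01 ± 0.11 (exact permutation p = 0.9). Interferon-stimulated genes had a higher median response in Y147F than in WT, by 0.38 over 16 genes (adjusted p = 1.98e-05, and adjusted p = 0.709 with an estimated correlation), and so did 9 cholangiocyte markers by 0.37 (0.00266, and 0.709 with an estimated correlation), with none of their genes called by limma and 4 and 3 of them at an unadjusted p under 0.05. The interferon list differed from WT by a median of 0.35 in KO as well (0.00747, and adjusted p = 0.568 with an estimated correlation) and 0.35 in GS (0.0928). With T3 the list had a median of -0.37 in WT, with 2 genes lower and 6 adjusted over the list alone (list adjusted p = 0.0673), and of 0.04 in Y147F. For genes called in WT the score rose by 0.54 in Y147F, 0.13 in KO and 0.12 in GS, and for those that fell it changed by -0.45, -0.10 and -0.07. Y147F differed from KO by 0.41 and from GS by 0.42 on the first set and by -0.35 and -0.38 on the second (exact permutation p = 0.005 for each). With a 2-fold selection in WT these were 1.03 and 1.13, and -1.13 and -1.07. The Y147F arrays came in a later submission with another hypothyroidism protocol, so although each T3 response is taken within 1 submission, their difference also compares submissions. Within Y147F all 3 PBS arrays have title numbers over 100000 and most T3 arrays do not, so T3 partly goes with these numbers. With the title number as a covariate 1169 genes were called for T3 in Y147F, 1056 of them among the 1644.

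**Figure D3:**
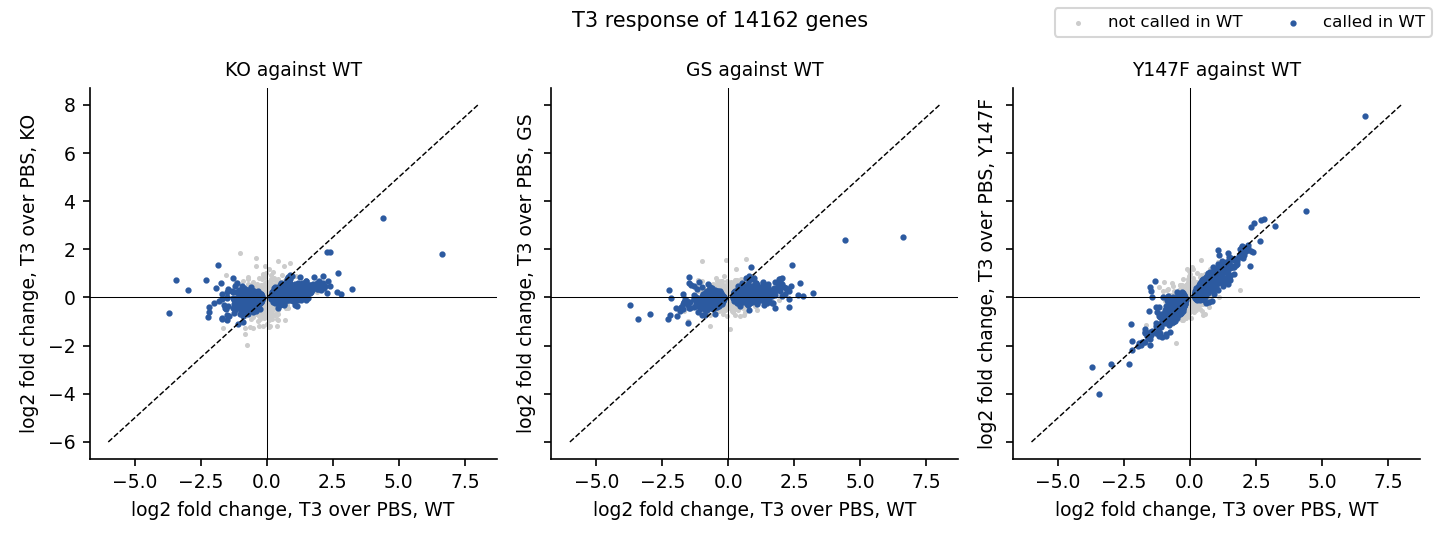
Log2 T3 response of 14162 genes in KO, GS and Y147F (vertical axes) against WT (horizontal axis); each point is a gene, blue where it was called in WT, and the dashed line marks equal responses. Pearson's r across genes was 0.357 for KO, 0.313 for GS and 0.800 for Y147F.

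The PBS groups compare genotypes in hypothyroid mice given no hormone. KO livers had more of the sulfotransferase Sult2a8 (2.78 ± 0.33), the glucuronosyltransferase Ugt2b38 (2.52 ± 0.54), the organic anion transporter Slc22a7 (2.44 ± 0.25), Mup10 (2.39 ± 0.44), the leptin receptor Lepr (2.19 ± 0.41) and the apolipoprotein Apoa4 (2.11 ± 0.37) than WT. They had less of the metallothioneins Mt2 (-3.19 ± 0.54) and Mt1 (-3.01 ± 0.49), Nipal1 (-2.92), the fatty acid hydroxylase Cyp4a14 (-2.25), Acot3 (-2.15), Olig1 (-2.88), the protease inhibitor Serpinb1a (-2.10) and the chemokine Ccl27a (-1.96). Of the 17 T3 targets 6 were higher and 1 lower (8 and 1 adjusted over the list alone), including Gpd2 (1.45), Dio1 (1.24), Bcl3 (1.03), G6pc (0.83), Idh3a (0.74) and, lower, Ppargc1a (-0.69). The list's adjusted p was 1.10e-04 (0.0465 with an estimated correlation). Male-biased liver genes had 5 of 10 higher, 8 adjusted over the list alone (5.16e-06, and 0.0465 with an estimated correlation), with Cyp7b1 at 0.88, Cyp2u1 at 0.68 and Cyp2d9 at 0.33. Bile acid and sterol disposal had 5 of 16 higher, 8 higher and 1 lower adjusted over the list alone (6.57e-05, and 0.0246 with an estimated correlation), with Cyp27a1 at 0.65, Scarb1 at 0.72 and the canalicular exporters Abcb4 at 0.69 and Abcb11 at 0.53. Immediate early genes had 3 of 12 higher, Fos (2.03), Dusp1 (1.99) and Hspa1b (1.72; adjusted p = 0.0375, and adjusted p = 0.602 with an estimated correlation). Kupffer cell markers were higher beside them, with a median of 0.22 and 1 of 13 called, 2 adjusted over the list alone (adjusted p = 0.0325, and adjusted p = 0.771 with an estimated correlation).

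Limma called 973 genes in KO without T3, 533 higher and 440 lower, 88 of them at least 2-fold and 954 with non-overlapping groups, against 23.6% of all genes where chance gives 10%. The count was 382 with only the 6 arrays compared, 523 without the KO PBS replicate 3, 642 without the KO PBS replicate 2 and 581 without the WT PBS replicate 2. With the title number as a covariate more genes were lower than higher (343 and 310). Fos lost its call in 5 of the 6 fits that left out 1 array, and Ccl27a lost its call without the KO PBS replicate 2 (adjusted p = 0.0549).

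GS livers without T3 also had more Sult2a8 (2.70 ± 0.33), Slc22a7 (2.59 ± 0.25), Mup10 (2.13 ± 0.44) and Lepr (1.97 ± 0.41) than WT, and less Serpinb1a (-1.81 ± 0.24). Tlcd2 (2.02), the amino acid transporter subunit Slc3a1 (1.82), Mmd2 (1.80) and Rarres1 (1.78) were higher, and Ppp1r3g (-2.41), Nr4a1 (-2.07), the keratin Krt23 (-2.07), the DNA repair nuclease Dclre1a (-1.35), the acyl-CoA thioesterase Acot1 (-1.33), Pla2g12a (-1.27) and thyroxine-binding globulin Serpina7 (-1.26) were lower. The T3 targets had 5 of 17 higher, 8 higher and 1 lower adjusted over the list alone (1.80e-07, and 0.00926 with an estimated correlation), Gpd2 (1.41), Bcl3 (1.11), Dio1 (1.09), Me1 (0.82) and Idh3a (0.69). Bile acid and sterol disposal had 6 of 16 higher, 7 higher and 1 lower adjusted over the list alone (6.34e-05, and 0.0142 with an estimated correlation), with Cyp27a1 at 0.65 and Scarb1 at 0.56. For cholesterol synthesis 1 of 20 was called, Sc5d (0.62), and 9 adjusted over the list alone (2.14e-06, and adjusted p = 0.481 with an estimated correlation). Periportal hepatocyte genes had 2 of 10 higher, Ctsc (1.61) and Cyp2f2 (0.73), and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00361, and adjusted p = 0.0917 with an estimated correlation). The calls numbered 418, 279 higher and 139 lower, 53 of them at least 2-fold and 413 with non-overlapping groups, against 20.4% of all genes where chance gives 10%. The count was 211 with only the 6 arrays compared and 671 with array weights, and 261 without the WT PBS replicate 1, 260 without the WT PBS replicate 2, 246 without the GS PBS replicate 1, 274 without the GS PBS replicate 2 and 235 without the GS PBS replicate 3. Dio1 lost its call without the WT PBS replicate 2 or 3 or the GS PBS replicate 1 or 2 (adjusted p from 0.124 to 0.175), and Ppp1r3g and Serpina7 lost theirs in 4 of the 6 fits that left out 1 array. Lepr lost its call without the GS PBS replicate 1 (adjusted p = 0.0647) and Nr4a1 without the WT PBS replicate 2 (0.0663).

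KO and GS shared 212 genes called higher than WT without T3, where 10.5 would be expected, and 98 called lower, where 4.32 would be expected, with none called in opposite directions. Both differences use the same WT arrays, which alone made simulated differences correlate at 0.505, against 0.703 across genes here. Compared directly, GS had more of the phenol sulfotransferase Sult1a1 than KO (0.78 ± 0.10, adjusted p = 0.00133) and less Hspb1 (-1.01 ± 0.12, adjusted p = 0.000416) and Nkiras1 (-0.81 ± 0.09, adjusted p = 0.000239), an inhibitor of NF-κB signalling. Mccc1 (0.66), Arf5 (0.59), Gstm6 (0.52), Slc2a9 (0.48), Sult1b1 (0.47) and Gamt (0.37) were also higher, and Ttc39a (-1.31), Col27a1 (-0.58) and Msrb3 (-0.56) lower, and these 9 lost their calls in at least 1 fit that left out 1 array. These were the 12 calls, 7 higher and 5 lower, all with non-overlapping groups, against 14.4% of all genes where chance gives 10%. Immediate early genes lay lower in GS than in KO, with a median of -0.36 over 12 genes (6.79e-07, and adjusted p = 0.155 with an estimated correlation), and 5 were lower adjusted over the list alone. Markers of other cells were also lower, with a median of -0.26 over 12 stellate cell markers (9.35e-04, and adjusted p = 0.231 with an estimated correlation) and -0.22 over 13 Kupffer cell markers (0.00829, and adjusted p = 0.758 with an estimated correlation), none called by limma and 4 and 2 at an unadjusted p under 0.05. In all 10 lists passed with the preset correlation and none with an estimated one. The marker differences rest on the same KO PBS arrays as the lower marker medians with T3 in KO, and that of Hspb1 on the same arrays as its fall with T3 in KO. The count was 22 without the KO PBS replicate 1 and 3 without the GS PBS replicate 2 or 3, and over the settings tried it ran from 2 to 45.

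Few genes were called between Y147F and WT without T3, but 1956 had an unadjusted p under 0.05, close to the 2003 of GS against WT. The few calls therefore do not show that the groups were alike. Papss1, which makes the sulfate donor for sulfation, was lower (-1.08 ± 0.15, adjusted p = 0.00987), as were Erdr1 (-2.21 ± 0.37), the receptor Hcar2 (-0.83), Snhg6 (-0.81) and Lce3b (-0.41). The kinase gene Sbk1 (0.85 ± 0.16), the urate transporter Slc2a9 (0.49), Fn3k (0.47), Pdp2 (0.45), Stat5b (0.45) and Cyb5d1 (0.29) were higher. Cholesterol synthesis genes had a median of -0.40 over 20 genes with none called by limma and 8 at an unadjusted p under 0.05 (list adjusted p = 2.59e-05, and adjusted p = 0.752 with an estimated correlation). Neutrophil markers had a median of -0.17 over 8 genes, none called by limma and 2 at an unadjusted p under 0.05 (0.0454, and adjusted p = 0.752 with an estimated correlation). Limma called 12 genes, 6 higher and 6 lower, with non-overlapping groups for all 12, against 17.7% of all genes where chance gives 10%. These arrays were submitted later, from mice that were older and given other doses of the antithyroid drugs, so genotype and submission cannot be told apart here. Each of the 12 lost its call in at least 2 of the 6 fits without 1 array, and the count was 1 without the WT PBS replicate 2, 0 without the WT PBS replicate 3 or the Y147F PBS replicate 2 (1715 and 1912 with an unadjusted p under 0.05), 3 without the Y147F PBS replicate 3 and 23 without the Y147F PBS replicate 1.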

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

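Of the tests in this part, those of remaining hormone and of the title numbers were chosen after the result was seen, as was the score of the T3 targets over all genotypes. The T3 response differed between genotypes by a test of the difference itself for 437 genes in KO against WT and 414 in GS against WT.

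Among genes that T3 raised in WT, the response in KO was smaller for Dio1 (-4.80), Frmd8 (-2.84), Bcl3 (-2.67), Bmf (-2.43), Slc22a7 (-2.10), Gpd2 (-1.90), Ighm (-1.79) and Idh3a (-1.74). The sizes for Dio1, here and in GS, rest on a WT level without T3 near background. It was higher for Acot3 (4.16), Nipal1 (3.27), Mt1 (3.19), Socs2 (3.08), Mt2 (3.04), Slc16a5 (2.33), Cers6 (2.31) and Cish (2.10), which T3 lowered in WT. In GS the same sign held for Dio1 (-4.11), Frmd8 (-3.03), Bcl3 (-2.75), Slc22a7 (-2.70), Bmf (-2.54), Slc25a45 (-2.09), Gadd45a (-2.06) and 9030619P08Rik (-2.02). Differences above 0 in GS were those of Socs2 (3.42), Nr4a1 (2.56), Acot3 (2.55), Cd24a (2.34), Nipal1 (2.31), Inhbe (2.16), Scara3 (2.10) and Dclre1a (1.83). Leaving out 1 array ended the call of Cish and Ighm in 7 of 12 fits and of Mt2 in 6 for KO, and for GS that of Acot3 in 11, Cd24a in 10, Scara3 in 9, and Nipal1 and Nr4a1 in 4. Part of these differences lies in the PBS groups. Without T3, KO already stood below WT for Mt1, Mt2, Nipal1 and Acot3 and above it for Slc22a7, Gpd2, Bcl3 and Idh3a. GS stood below WT for Nr4a1 and Dclre1a and above it for Slc22a7 and Bcl3. Slc22a7 ran from 9.6 to 10.4 in KO with PBS and from 10.0 to 10.4 in KO with T3, against 9.6 to 10.0 in WT with T3.

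The scores differed as well. For genes called higher in Y147F, KO and GS each lay -0.47 from WT, and for genes called lower 0.32 and 0.32. For genes called higher in WT, Y147F exceeded KO by 0.41 and GS by 0.42, and for genes called lower the differences were -0.35 and -0.38. On the 17 T3 targets KO lay -1.01 and GS -1.15 from WT, and Y147F lay 1.02 above KO and 1.16 above GS. All 12 had an exact permutation p of 0.005, the smallest possible.

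Of 4118 tested probe sets without a single gene symbol, which entered no comparison, T3 called 126 in WT, 71 higher and 55 lower. The largest called rise among them was 6.05 and the largest fall -4.81. The counts were 163 in Y147F, 4 in GS and 0 in KO by limma, where 225 had an unadjusted p under 0.05.

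Chance assignment of the arrays was checked by exchanging genotype labels within each treatment. Of 200 distinct assignments 100 were drawn, the real one among them. For KO against WT 2 of these 100 gave as many genes as the real 437, the real one included, and for GS against WT 2 of 100 gave as many as 414. Both shares lie under 0.05, which argues against a chance assignment but does not exclude it. Exchanging labels cannot address a cohort that goes with genotype. The highest other counts were 1728 and 847, from the assignment that exchanges all labels in 1 treatment and so measures the average genotype difference, a structure of these samples; without it the highest were 395 and 172. For Y147F against WT and GS against KO, where the real count was 0 by limma with 756 and 809 genes at an unadjusted p under 0.05, all 100 of 100 gave as many, as a count of 0 makes certain, so this says nothing about chance; the highest other counts were 115 and 66, and 2 and 12 without the assignment that exchanges all labels in 1 treatment. Single comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05, and the real split, 1 of 10, stood alone each time. With T3 the real and highest other counts were 1505 and 2 in WT, 25 and 4 in KO, 21 and 4 in GS, and 1644 and 1 in Y147F. Without T3 they were 973 and 3 for KO, 418 and 0 for GS, 12 and 0 for Y147F, and 12 and 0 for GS against KO.

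The pattern weighed here is that genes raised by T3 already stood higher in KO and GS than in WT without T3, by 0.21 ± 0.03 and 0.23 ± 0.03 in the score. A batch marked by the title numbers is argued against for GS, which lay 0.198 ± 0.0322 above WT within numbers up to 100000 (2 arrays of each), where such a batch alone would leave 0, beside 0.226 for all arrays. For KO it cannot be told apart within KO and WT, because all 3 KO PBS arrays have higher numbers and only 1 WT PBS array does, from which they differed by 0.26. All 3 Y147F PBS arrays have higher numbers too. On the T3 targets these lay 0.05 ± 0.10 from WT and -0.37 ± 0.11 from KO, and on genes called higher in WT -0.1205 ± 0.0065 from KO. This argues against such a batch as the whole cause in KO, though Y147F came from another submission and protocol. Remaining thyroid hormone in the mutants cannot be told apart from a loss of receptor action, since the genes chosen to tell them were few and not all rose in Y147F. Those that T3 raised in GS by at least 0.75 of their change in Y147F had a median of -0.0208 (-0.09 to 0.16, 9 genes) in KO without T3. Those chosen likewise from KO had -0.0613 (-0.28 to 0.31, 11 genes) in GS. These intervals come from resampling the genes and give no spread over mice. The choice let in genes that hardly rose with T3 in Y147F and WT, such as Adgre5 (0.04 and 0.02), or did not rise, such as Tango2 (-0.16 and -0.05). Such genes can tell little about remaining hormone. Both intervals are too wide to exclude the 0.15 and 0.16 of the 782 genes, and a response kept in 1 mutant need not be kept in the other. Release from repression by TRβ without hormone may account for the pattern. It predicted that the difference grows with a gene's T3 response, and across the 782 genes the 2 correlated at 0.518 in KO (Spearman 0.346) and 0.578 in GS (0.435). Remaining hormone might give such growth as well, which was not tested, so these correlations do not favour either explanation. Genes are not independent replicates, and the T3 responses in these correlations came from Y147F arrays that enter neither difference. In KO, T3 raised the 782 genes by 0.12 ± 0.01, less than the 0.21 ± 0.03 by which they stood above WT. That rise would come on top of any hormone already acting, so it does not decide between the explanations.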

How the results depend on the processing

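Tests added after the data were seen are the fit of first-submitted arrays and the list tests on only the arrays compared. Counted as pairs of a named gene and a refit, genes called in the main fit changed sign in none of 6679, and those not called in either fit did so in 349 of 21613. Of 12 score results, the 8 that set KO or GS against WT or Y147F kept their direction and their side of the threshold under the median, a 2-fold selection, quantile normalisation and leaving out each array. Their size grew with the 2-fold selection, which keeps genes with large responses by construction. It was -1.18 (KO) and -1.24 (GS) against WT for genes higher in Y147F and 1.27 and 1.13 for genes lower, and for Y147F against KO and GS 1.03 and 1.13 for genes higher in WT and -1.13 and -1.07 for genes lower. The 4 of GS against KO stayed uncalled and changed sign, running from -0.06 to 0.02 (genes higher in Y147F), -0.14 to 0.02 (lower in Y147F), -0.10 to 0.02 (higher in WT) and -0.06 to 0.06 (lower in WT). More genes fell than rose with T3 in Y147F, and the reverse held for the mean of probe sets (830 higher, 820 lower), the title number (660, 509), only the arrays compared (458, 406), the 2-fold threshold (109, 52), and without the PBS replicate 3 (702, 601) or the T3 replicate 1 (623, 463) or 2 (630, 568). For KO without T3 it turned with the title number (310, 343), and the larger side also varied between settings for the 12 calls of Y147F and of GS against KO without T3. The counts for T3 in WT and for both differences from WT stayed within 1.5 times under all settings but the 2-fold threshold. At that threshold, by construction, the counts were 192 in WT, 5 in KO, 5 in GS and 161 in Y147F for T3, 120 and 126 for the differences of KO and GS from WT, and 88 (KO), 53 (GS), 2 (Y147F) and 2 (GS against KO) without T3. With only the arrays compared, which leaves fewer degrees of freedom, T3 gave 6 in KO, 2 in GS and 864 in Y147F, and the genotypes without T3 382 (KO), 211 (GS) and 1 (Y147F). The lists past the test were then 8 for T3 in GS, against 5, and 5 for Y147F without T3, against 2. Array weights gave 33 for T3 in GS, and without T3 671 (GS), 33 (Y147F) and 45 (GS against KO). For Y147F without T3 the count was 3 after quantile normalisation, with 1 list past the test, 6 with no filter, 20 with trend and robust moderation and 1 with the title number. For GS against KO without T3 it was 25 after quantile normalisation, 23 with trend and robust moderation, 6 with the title number, 23 with the 60th percentile filter, 26 with the mean of probe sets and 6 with first-submitted arrays only. The cause was not tested for these. With the correlation estimated, the lists past the test fell, for T3, from 5 to 1 in WT, 11 to 0 in KO, 5 to 0 in GS and 6 to 1 in Y147F; for the differences of response, from 7 to 1 (KO), 6 to 1 (GS), 2 to 0 (Y147F) and 5 to 0 (GS against KO); and without T3 from 8 to 3 (KO), 7 to 2 (GS), 2 to 0 (Y147F) and 10 to 0 (GS against KO). That setting allows for members that vary together, by construction.

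Leaving out 1 array, which lowers the number tested on, gave 1075 to 1305 genes for T3 in WT, 16 to 31 in KO, 10 to 22 in GS and 1086 to 1659 in Y147F, and 331 to 400, 299 to 385, 0 to 1 and 0 to 1 for the differences of KO, GS and Y147F from WT and of GS from KO. The single calls came without the WT T3 replicate 3 and without the KO PBS replicate 2. Without T3 the ranges were 523 to 794 (KO), 235 to 314 (GS), 0 to 23 (Y147F) and 3 to 22 (GS against KO). For named genes, leaving out 1 array ended the call in 566 and brought one in 59 of 13590 pairs of a gene and a fit. Only the arrays compared ended 109 and brought 28 of 1728 such pairs. The pairs include genes not called in the main fit, which cannot lose a call. These shares are therefore lower than the rates of loss among called genes. No paired analysis was possible because the labels carry no number shared between samples, and every title number differs. Arrays give no depth, and the signal of dim probe sets over background limits what was tested.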

Other observations

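The tests of the Lrat and of the Thrb neighbour pattern below were chosen after the results were seen. Further genes of the fixed lists moved with T3. In WT the ribonucleotide reductase gene Rrm2 rose by 1.67 ± 0.23, and it rose by 0.98 ± 0.23 in Y147F. Of 20 cholesterol synthesis genes 2 rose and 1 fell in WT (list adjusted p = 0.62), with Hsd17b7 at 0.89 and Sc5d at 0.64 higher and the sterol carrier Stard4 at -0.51 lower. The stress gene Chac1 rose by 1.12 while Xbp1 fell (-0.45), and the same directions were called in Y147F (1.10 and -0.37). The chemokine Cxcl1 fell by 1.29 in WT. The interferon genes Rsad2 (-0.76) and Usp18 (-0.82) fell there too. The fatty acid elongase Elovl3 rose by 1.10 in WT and 1.78 in Y147F, and the male-biased Cyp2u1 by 1.49 and 1.67. The pericentral gene Lgr5 rose by 0.48 and 0.62, calls that were lost with the mean of its probe sets (adjusted p = 0.115 and 0.142).

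Without T3, KO livers had more of the hormone gene Fgf21 (1.18 ± 0.22) and of the acute phase genes Saa3 (0.98), Saa4 (0.46) and Hpx (0.24), and less of Acot1 (-1.66 ± 0.26) and Acadm (-0.39), which handle fatty acids. Of 22 acute phase genes 4 were higher, 5 adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.345 with an estimated correlation). Among xenobiotic genes Gsta2 (-1.07), Nr1i3 (-0.69) and Cyp2c55 (-0.64) were lower and Ces2a (0.50) higher, with the list at an adjusted p of 0.0213 (adjusted p = 0.536 with an estimated correlation). The periportal Ctsc (1.29), Cyp2f2 (0.71) and Cdh1 (1.49) were higher and the pericentral Oat lower (-0.68), with neither list past its test (adjusted p = 0.42 and 0.735). Of 7 female-biased genes Acot3 (-2.15) and Fmo2 (-1.15) were lower and none higher (list adjusted p = 0.0952). Slco1a1, a transporter of organic anions, was higher (1.77) and its relative Slco1a4 lower (-0.98).

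Lrat, a marker of stellate cells, rose with T3 by 1.61 in GS and 1.33 in KO. More stellate cells in the T3 samples are argued against, since the 11 other stellate and fibroblast markers had a median T3 change of -0.0368 in GS (-0.13 to 0.10) and -0.32 in KO (-0.64 to -0.13). These intervals come from resampling the 11 genes, which were read on the same arrays, and give no spread over mice. The largest rise among the 11 in GS was 0.18 (Rgs5). Abundant markers, such as Dcn with a WT PBS mean of 12.23 and Reln with 11.14, changed by 0.05 and -0.11 in GS. A change of Lrat within cells stays open and was not tested, and a lower level of Lrat without T3 in both mutants, by -1.15 in KO and -1.13 in GS, is part of the same rise.

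Nkiras1, which lies near Thrb, was higher in KO without T3 than in WT (1.03 ± 0.09) and led to a test of its neighbours. Of the 100 tested genes nearest to Thrb, leaving out both, 14 were called in KO, against 6.86% of all genes tested (Fisher's exact two-sided p = 0.00901), among them Ptprg, Fhit, Psmd6 and Thoc7. Of 131 windows of 100 genes, 2 held as many calls, with a median of 7 and a highest of 15. In GS 5 of the 100 were called (exact p = 0.223) and in Y147F 0 by limma, where 14 had an unadjusted p under 0.05. Fhit, Il17rb and Nek4 were called in both KO and GS. Without T3, Il17rb, Nek4 and Pdhb lay from WT, in KO and in GS, in the direction of their T3 change in WT (-0.82, -0.56 and 1.15). Lrtm1 and Ube2e1, also called in KO, went against theirs there. DNA of the strain in which the knockout was made, carried along beside the deleted gene, may account for part of these calls. An effect of the deletion itself on nearby genes, or of lost receptor action on genes that respond to T3, was not separated from it.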
